A study of Drosophila melanogaster with 3 samples.

How the data were processed

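Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos collected 8 to 24 h after laying, from flies carrying a transgene for the protein H15 fused to enhanced green fluorescent protein (eGFP). Per the labels, the fusion protein was precipitated with an anti-GFP antibody and chromatin was sheared by sonication, with a size range of 200 to 800. There was 1 group of 3 biological replicates, numbered as in the labels, and no other group to compare it with. A second age field of the labels gave a value too large for an embryo, so the collection window given with the strain was used.

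The files were lists of peaks, without reads, coverage or read numbers, so the depth per library is unknown and no interval that needs it is given. For each replicate the authors deposited 1 ranked list of all peaks that entered the irreproducible discovery rate (IDR) procedure, which scores how well the ranks of peaks repeat between compared sets, and 1 thresholded list. For the whole series they deposited 4 ranked lists and 4 thresholded lists, 1 of them called conservative. Per the notes deposited with the libraries, the lists of the whole series derive from the alignments of all 3 replicates and a control, and no note names which sets were compared in which list. They are therefore reported as the authors' lists, with no replicate error. The aligner, the peak caller and their versions are not given in the sources used here. The control library was not analysed here.

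Each peak has a signal value that the authors' peak caller gave it. Its scale is not stated, so the deposited signal was used to rank and compare peaks within a list, and levels of separate lists were not compared. The ranked lists also give the −log10 of the IDR of each peak, as deposited by the authors. The score of each of the 838590 ranked peaks equalled the score computed from that value to within 1. Every peak of the replicates' thresholded lists was in the ranked list and had a score of at least 830, an IDR of 0.01.

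The labels name the build dm6. Coordinates were compared with the Release 6 genome of RefSeq and the Ensembl BDGP6.54 annotation, release 115. Of 858063 peaks over all lists, 842156 (98.1%) lay on the 7 chromosome arms and chromosomes 2L, 2R, 3L, 3R, 4, X and Y, and 0 of these extended past the end of the reference sequence. Peaks on other sequences were counted but left out of the tests on genes, sequence and chromosomes, because their names were not mapped to the reference. All positions below are 1-based dm6 coordinates.

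A region was a merged set of windows of 100 bp on each side of the peak summits of the 3 thresholded lists, and it was shared when each replicate had a summit in it. Its centre was the median summit. Sharing was tested against 1000 draws in which as many peaks as in each thresholded list were taken at random from the same replicate's ranked list. Control peaks were 132971 merged windows of the replicates' ranked lists at least 1 kb from every thresholded peak of any list. For sequence tests, up to 5 control peaks per region were matched on GC decile and on lying within 500 bp of an annotated transcription start site, which gave 5622. Motifs, 7-mers (both strands joined), annotation classes and chromosomes were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family. Annotation class went first to regions within 500 bp of a start site, here called promoters, and otherwise by the feature under the centre.

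Each region was assigned to the nearest start site of a protein-coding gene within 20 kb. For 24 gene lists, the number of members with a shared region was compared with 10000 random lists of the same size, matched on decile of the number of bases nearest to each gene's start sites. These permutation tests were two-sided and adjusted over the 24 lists. The smallest p they can give is 0.0002. Of the symbols written in the lists, 4 were not matched to the annotation by symbol or by an unambiguous synonym. Correlations of signal between replicates were computed across regions, which are not independent replicates, with 10000 resamples. The relation of rank to the T-box core used 100000 resamples.

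The design, the gene lists, the motifs and 78 alternative settings were fixed before the data were examined, and 5 alternatives were added afterwards. Named genes were chosen by a fixed rule. It took the T-box genes, the nearest genes of the 10 regions with the best mean rank, the 10 genes with the most regions (ties by best mean rank), and up to 4 members per list with the most regions. One gene that the rule takes is not reported here. The 10 7-mers with the smallest p were named in each direction. The positional profiles of words, the shared 5-base core of the leading words, and the regional densities around H15 and mid were chosen after the data had been seen.

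The scripts were tested on simulated data. Among 8192 7-mers, 5 different words were planted together in control windows standing for regions, in a single scan per rate. Planted in 2% of the windows, 0 of the 5 words were recovered, and in 5% or 10%, 5 of 5. With nothing planted, 0 words were called in a single draw of control windows against others, without matching on GC or promoter class. For gene lists, regions at random positions gave 1 call in 480 list tests. Random positions are not concentrated at start sites, whereas 51.8% of shared regions lay within 500 bp of one. This rate of calls therefore does not cover regions placed as the shared ones are. The EGFR list of 12 members was called in 3 of 20 runs when 5 members were given a region, and in 20 of 20 when 8 were, the second strength having been added after the first was mostly missed. An effect of moderate size on a short list can therefore be missed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.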

Results

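The data are peaks of anti-GFP chromatin immunoprecipitation from Drosophila embryos aged 8 to 24 h that carried H15-eGFP, a tagged form of the T-box protein H15. The control library was not analysed here, so the peaks were not tested for being specific to the fusion protein. T-box proteins are transcription factors with a shared DNA-binding domain, and H15 and its neighbour and paralogue mid (midline) act in the heart, the nervous system and the epidermis. One group of 3 biological replicates was available. The thresholded lists held 1573 peaks in replicate 1, 1954 in replicate 2 and 2657 in replicate 3, out of ranked lists of 92149, 79650 and 87289 peaks. The median peak width was 290, 304 and 296 bp in these lists. The number of reads behind each list is unknown.

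The first comparison asked which regions were found in every replicate. The strongest of them was the same in all 3 lists and lay at the start of Ugalt, which encodes a transporter of UDP-galactose, on X from 2703777 to 2703991. The next 3 also held ranks 2, 3 and 4 in every list. They lay near CG14100 (3L, 19590513 to 19590721, 91 bp from a start site), in an intron near CG11050 (2L, 6612602 to 6612820) and near mRpL41, a gene for a mitochondrial ribosomal protein (2R, 15217632 to 15217866, 144 bp from a start site). The signal of the Ugalt region was 724 in replicate 1, 761 in replicate 2 and 1056 in replicate 3, each the highest of its list.

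The other 6 of the 10 best regions by mean rank were near Tcs5, CG7601, ph-p, CenG1A, CG13323 and Chro. The gene ph-p encodes a Polycomb group protein, and its best region lay in an intron on X from 2137251 to 2137465, with ranks of 7, 6 and 5. Chro encodes the chromosomal protein Chromator, and its region lay 88 bp from a start site on 3L from 22878784 to 22878997, with a mean rank of 12. The regions of Tcs5 (3L, 5139377 to 5139593), CG7601 (3R, 29736750 to 29736953) and CenG1A (2L, 13835346 to 13835581) were promoter regions, with mean ranks of 6, 6 and 9.67. CG13323 was the nearest gene to an intergenic region on 2R from 13035237 to 13035441, at a distance of 11918 bp.

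Genes with several regions were also named. The gene chinmo, which encodes a BTB zinc finger protein of neural timing, had 5 shared regions assigned, as did Ids and CG7560. Tlk, a gene for a Tousled-like kinase, had 4. The genes with 3 regions and the best ranks were ph-p, CG4004, Trl, Sesn and Raf. Trl encodes GAGA factor, Sesn a sestrin and Raf a kinase of the receptor tyrosine kinase pathway. The best region of Tlk had a mean rank of 28.3, that of Trl 40 and that of Raf 101.

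In total, 3072 regions were found in any replicate, 1178 (38.3%) of them in all 3, 631 in 2 and 1263 in 1. The shared regions made up 76.3% of the regions of replicate 1, 61.7% of replicate 2 and 45.2% of replicate 3. Random draws from the ranked lists shared 0.406 regions on average and at most 3 (permutation test, one-sided, p = 0.001, the smallest that 1000 draws can give). With the top 500 peaks of each list the shared number was 354.

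**Figure D1:**
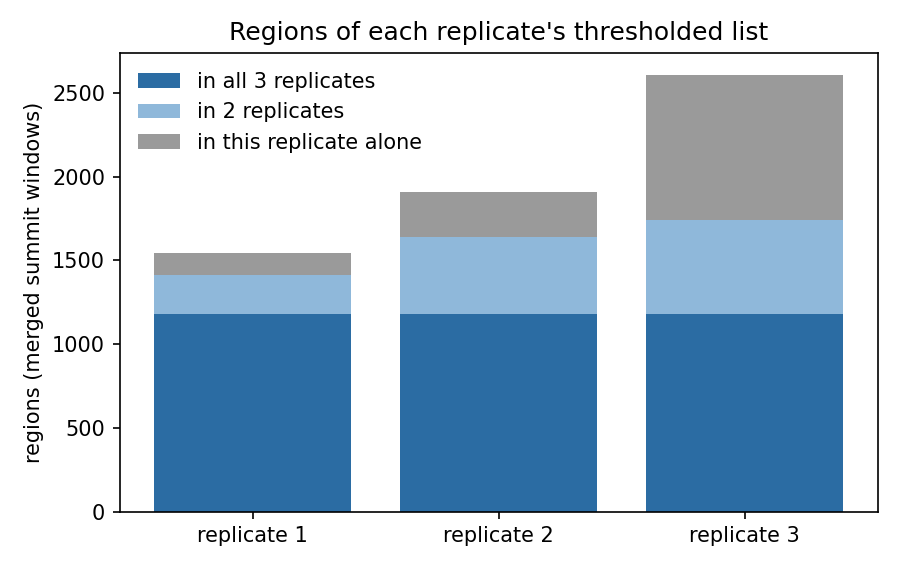
Bars give the number of regions (merged windows around peak summits) of each replicate's thresholded list, split into regions of all 3 replicates, of 2 and of that replicate alone. The 1178 shared regions are common to the bars, while 866 regions were found in replicate 3 alone, against 129 in replicate 1 and 268 in replicate 2.

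The order of the shared regions by signal was similar between replicates. Ugalt, CG14100, CG11050 and mRpL41 led all lists, while the region of mid had ranks of 1395, 1373 and 1630 and that of piwi 1410, 1564 and 2427 in replicates 1, 2 and 3. Across the 1178 regions, Spearman's rho was 0.801 for replicates 1 and 2, 0.796 for replicates 1 and 3, and 0.821 for replicates 2 and 3, with Pearson's r of 0.952, 0.946 and 0.949. Each permutation p was 0.0001 before and after Benjamini-Hochberg adjustment over the 3 pairs, the smallest possible. These are correlations across regions of 1 group, and regions are not independent replicates.

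The next comparison asked where the regions lie relative to genes. Shared regions were found at promoters more often than control peaks, and rarely in coding exons over 500 bp from any start site. Ugalt, CG14100, mRpL41, Tcs5 and the ribosomal protein genes RpL7 and RpS27 had their regions at the promoter, while those of dpp, sog, Antp and Mef2 lay in introns or a 5′ UTR. The gene ph-p had 1 region at the promoter and 2 in introns. Of the 1169 shared regions on the chromosomes, 605 (51.8%) lay within 500 bp of a start site, against 13.4% of the 132971 control peaks (odds ratio 6.92, 95% interval 6.16 to 7.77, Fisher's exact test, adjusted p = 4.15e-210). The share was 49.1% ± 2.35 (SD, n = 3) of the peaks of each replicate's own list. Classes other than the promoter count only centres over 500 bp from any start site. Coding exons then held 4 of the 1169 regions (0.342%), against 19.5% of control peaks (odds ratio 0.0142, Fisher's exact test, adjusted p = 4.14e-101).

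Introns held 33.3% of shared regions and 38.1% of control peaks (Fisher's exact test, adjusted p = 0.00098), and intergenic sequence 12.7% and 24.5% (adjusted p = 2.43e-23). The 3′ UTR class held 5 regions (0.428%), against 2.70% (Fisher's exact test, adjusted p = 1.63e-08). The classes of 5′ UTR and of other exons did not pass the threshold (adjusted p = 0.194 and 0.42, Fisher's exact test). Of the 605 promoter regions, 512 (84.6%) had their centre upstream of the start site, and 358 (59.2%) lay up to 200 bp upstream. The median position was -124 bp. Positions relative to the start site were examined after the data had been seen.

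**Figure D2:**
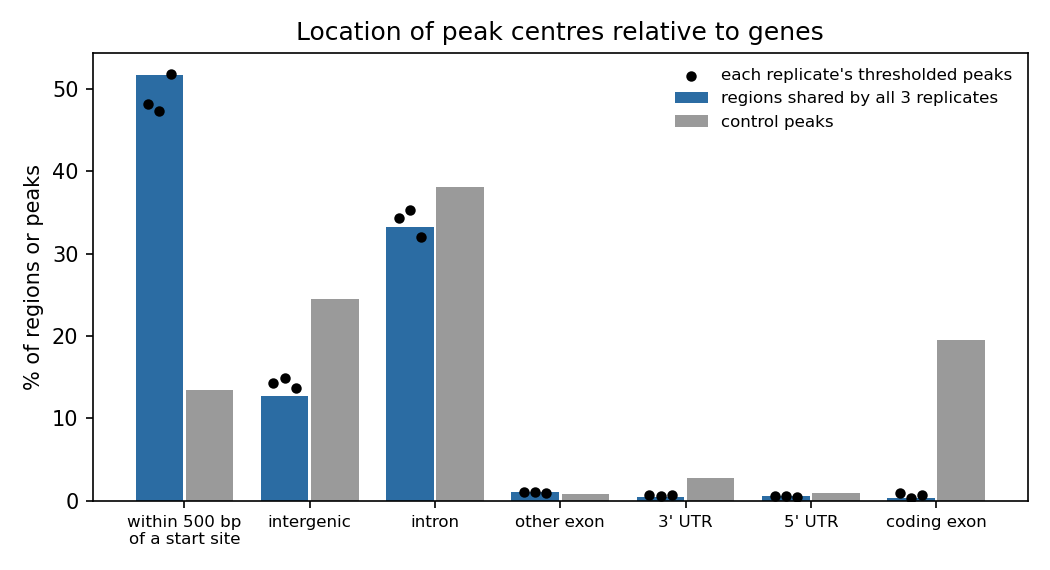
Bars give the percent of 1169 shared regions and of 132971 control peaks in each annotation class, and points give the percent of each replicate's thresholded peaks. The promoter bar of shared regions reaches 51.8% and that of control peaks 13.4%, with replicates between 47.4% and 51.8%.

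By chromosome, X held a larger share of shared regions than of control peaks, and 3R a smaller share. X carried 235 regions, 9.98 per Mb and 20.1% of the total, against 16.7% of control peaks (odds ratio 1.25, Fisher's exact test, adjusted p = 0.0132). Regions and control peaks on scaffolds with names that begin with X were not counted. Chromosome arm 3R carried 256 regions, or 21.9% against 25.6% of control peaks (odds ratio 0.815, Fisher's exact test, adjusted p = 0.0132). Its 7.98 regions per Mb were close to the 8.03 of 2R, which was not called. Control peaks were not matched on GC or promoter class here. They were at 1061 per Mb on 3R, 968 on 2R and 944 on X. The other arms did not pass the threshold. Chromosome 4 had 1 region, at the promoter of PlexA, a gene for an axon guidance receptor, and Y had 0. The call for X was lost with the longest IDR list of the series (odds ratio 1.02), and both calls were lost with the top 500 peaks.

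A further comparison asked whether shared regions hold the sequence that T-box proteins bind. They did not hold it more often than controls. The 7-base T-box core AGGTGTG was within 100 bp of the centre of 11 of 1169 shared regions (0.941%) and of 91 of 5622 matched control peaks (1.62%), an odds ratio of 0.577 (95% interval 0.308 to 1.08, Fisher's exact test, p = 0.0864, adjusted p = 0.38 over 22 motifs). The share in the replicates' own lists was 1.33% ± 0.101 (SD, n = 3). The same word reversed, a control for composition, was in 1.37% of regions and 1.83% of controls (Fisher's exact test, adjusted p = 0.617). With GGTGTGA as the motif the odds ratio was 1.28 (Fisher's exact test, p = 0.374), and against flanking windows of the same regions it was 0.444 for AGGTGTG (p = 0.0125).

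Of the 22 fixed motifs, only the GAGA repeat bound by the Trl protein passed the threshold. It was in 132 shared regions (11.3%) and 6.53% of matched controls (odds ratio 1.82, 95% interval 1.48 to 2.25, Fisher's exact test, adjusted p = 1.51e-06), and in 11.1% ± 0.586 (SD, n = 3) of the replicates' own peaks. The Ets motif (3.76% against 2.37%, Fisher's exact test, adjusted p = 0.0938) and the Mef2 motif (13.0% against 10.7%, adjusted p = 0.177) did not pass it, nor did the motifs of Tinman, GATA factors, forkhead proteins, Zelda or the homeodomain.

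Within each list, stronger peaks did not hold the T-box core detectably more often than weaker ones. Spearman's rho between signal and presence of AGGTGTG was -0.0418 in replicate 1, -0.0202 in replicate 2 and -0.0227 in replicate 3 (permutation tests, two-sided, adjusted p = 0.304, 0.375 and 0.366). The core was in 22, 26 and 32 peaks of these lists.

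A search over all 7-mers asked which words mark the shared regions without a prior motif. The words that rose most were related to each other, and 7 of the leading 10 contained the core CAGTG or its complement. ACAGTGG was in 152 shared regions (13.0%) and 2.24% of matched controls (odds ratio 6.52, 95% interval 5.10 to 8.33, Fisher's exact test, adjusted p = 5.80e-44). It was in 11.0% ± 0.887 (SD, n = 3) of the replicates' own peaks. CACAGTG followed with 11.2% against 2.79%, CACTGTA with 8.90% against 2.38%, and CAGTGTA with 8.64% against 2.35%. The remaining 6 of the leading words were CACTGAG, ACTGTGC, ACTGTAC, CAGTGCA, AGTGCAC and CAGTGGG, with odds ratios from 2.67 for CAGTGCA to 4.40 for CACTGAG.

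Of 8192 7-mers, 141 were higher in shared regions and 42 were lower. The lower words with the smallest p were ATTTGCC (2.05% against 5.02%, adjusted p = 0.000356, Fisher's exact test), ATTTTCG (4.11% against 7.74%), AAGGACA (0.684% against 2.67%), CAAAGGA, CAAAAAA, TGGCCAA, CCAGCCA, AAATTGC, TGATGAA and GCAGGAA. Among the 22 7-mers that contain GGTGTG, GTGTGA or AGGTGT, 0 were called in either direction, and 2 had an unadjusted p under 0.05. The number of words called higher ranged from 43 to 1380 over the alternatives, and the number lower from 3 to 2224. The top 500 peaks gave the lowest of each and unmatched controls the highest. Without matching, and against flanking windows (735 higher, 960 lower), more words were lower than higher. Without replicate 1, 239 were higher and 138 lower, and without replicate 2, 66 were lower. ACAGTGG was higher under each setting in which 7-mers were tested, with odds ratios from 2.44 at 50 bp on each side (Fisher's exact test, adjusted p = 0.0303) to 14 with the top 500 peaks. At 50 bp only 2 of the 10 leading words were higher and TTAAAAA led, while TAAAATA led against flanking windows and without matching.

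**Figure D3:**
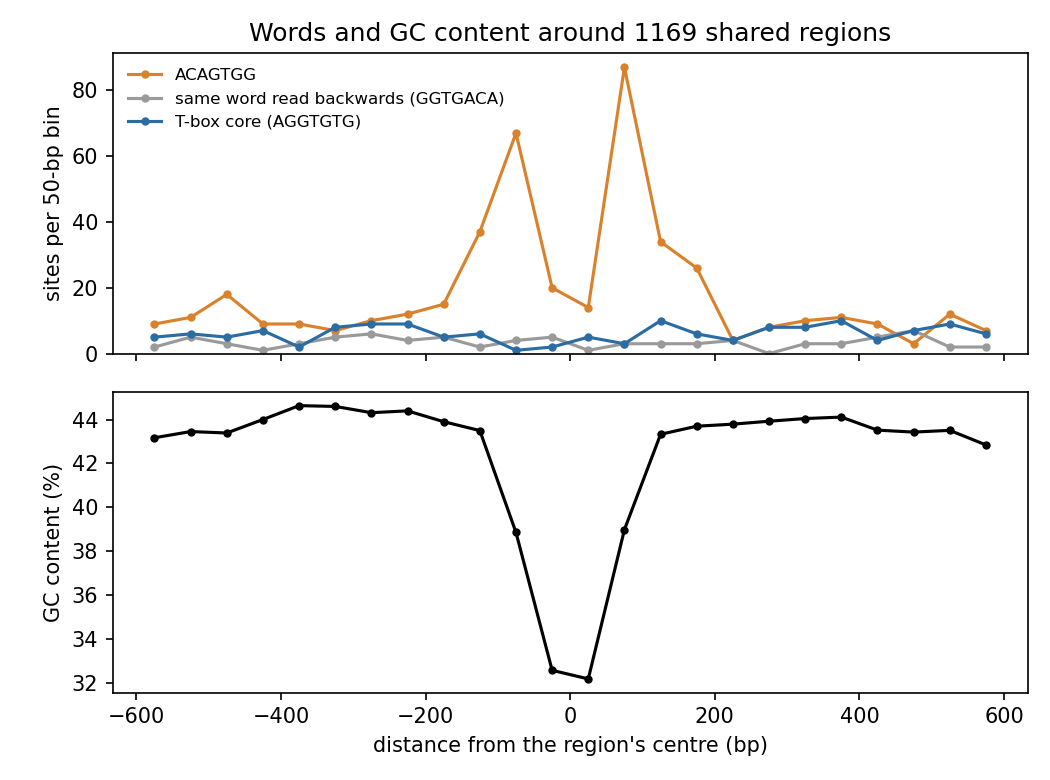
The upper panel gives the number of sites per 50-bp bin, by distance in bp from the centre of 1169 shared regions, for ACAGTGG, for the same word read backwards and for the T-box core, and the lower panel gives the GC content in percent. ACAGTGG peaks at 87 sites between 50 and 100 bp on the right and 67 between 50 and 100 bp on the left, around a dip of GC content to 32.2%.

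Gene lists were compared to ask which groups of developmental genes had shared regions nearby. Ribosomal protein genes, genes of the EGFR pathway, T-box genes and genes of the heart and dorsal mesoderm had more members with a shared region than matched random lists. Of 93 ribosomal protein genes, 25 had a region, against 5.11 in random lists (permutation test, adjusted p = 0.0048, from the smallest p possible), and each of the 25 had one at a promoter. RpL7 (32 bp from a start site), RpS27 (11 bp), RpL34b (83 bp) and RpL14 (47 bp) had the best ranks of this list.

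Of 12 EGFR pathway genes, 7 had a region, against 1.69 in random lists (permutation test, adjusted p = 0.0072). Star (S), which acts in ligand processing, had 3, and the repressor gene aop and the inhibitor gene sty had 2 each. The inhibitor gene aos had 1, in an intron on 3L from 16480472 to 16480695 with a signal of 134, 195 and 215 in replicates 1, 2 and 3. Only 1 of the 7 members had a promoter region.

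Of 8 T-box genes, 5 had a shared region, against 0.92 in random lists (permutation test, adjusted p = 0.0096). Several members are close together, Doc1, Doc2 and Doc3 on 3L from 9005196 to 9045042, and H15 and mid on 2L. The random lists were not matched on this, so the members are not independent and the p may be too small. The region of org-1 was the strongest of them, 347 bp from a start site on X from 8455293 to 8455521, with a signal of 177, 164 and 242 in replicates 1, 2 and 3. Doc2 (3L, 9025777 to 9026012) and Doc1 (3L, 9034318 to 9034563) had intergenic regions 6666 and 6925 bp from a start site. Both regions lay between Doc2 and Doc1. The region of bi lay in an intron on X from 4446175 to 4446395, 19141 bp from a start site. The region of mid lay 8359 bp from its start. H15 itself, byn and Doc3 had 0 under the limit of 20 kb. The shared region on 2L from 5425410 to 5425611, between H15 and mid, was assigned to neither gene. With no distance limit, 6 of the 8 genes had a region.

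Of 23 genes of the heart and dorsal mesoderm, 9 had a region, against 2.77 in random lists (permutation test, adjusted p = 0.012). The heart gene tin had a region 189 bp from a start site on 3R from 21378682 to 21378904, with ranks of 272, 151 and 200. The GATA cofactor gene ush had 3 regions, the best of them in an intron on 2L from 522003 to 522248, and zfh1 had 1 in an intron on 3R from 30781684 to 30781908. Some members are also T-box genes, Doc2 among them, so the heart and T-box calls share regions and are not independent. The heart list also holds H15 and mid, which are close together, so its p may be too small as well. With H15 and mid left out of every list, an alternative added after the data had been seen, 4 of 6 T-box genes and 8 of 21 heart genes had a region (adjusted p = 0.0192 for both, permutation tests). The 4 T-box genes still included Doc1 and Doc2, which are close together.

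Which lists were called changed with the way regions were assigned, matched and thresholded. With gene bodies extended by 5 kb, the T-box, heart and EGFR calls were lost (adjusted p = 0.787, 0.526 and 0.17, permutation tests). The ribosomal list was still called there, and 3 others were gained, the Notch pathway with 12 of 17 members, the Dpp pathway with 10 of 14 and mitochondrial ribosomal protein genes with 19 of 73 (adjusted p = 0.0024, 0.0064 and 0.0276, permutation tests). Without matching on territory length, the Notch and Dpp lists were called besides the 4 (adjusted p = 0.0456 and 0.0163, permutation tests). With regions within 1 kb of a start site alone, only the ribosomal list was called, and the ratio of the heart list fell to 0.706. With the longest IDR list the T-box and heart calls were lost (adjusted p = 0.0872 for both, permutation tests), and with the top 500 peaks, where fewer regions enter, 0 lists were called. The ratios to random lists were then 7.01 for T-box, 5.96 for EGFR, 3.50 for heart and 3.97 for ribosomal genes, beside 5.44, 4.15, 3.24 and 4.89 with all shared regions.

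With the settings fixed for the report, the other 20 lists did not pass the threshold. The nearest were the Notch pathway with 5 of 17 members (adjusted p = 0.0616, permutation test), odorant and gustatory receptor genes with 2 of 117 against 8.37 in random lists (adjusted p = 0.0616), and the Dpp pathway with 5 of 14 (adjusted p = 0.085). The 5 members of the Notch list included numb, neur, E(spl)malpha-BFM and E(spl)m3-HLH. The 5 of the Dpp list included shn, which had 2 regions, and Mad, dpp and sog. In the receptor list they were Gr89a and Gr93a. This list was called lower without replicate 1 or 2 (adjusted p = 0.0096 and 0.0355, permutation tests), with the conservative list (0.0024), the longest list (0.0016) and regions of at least 2 replicates (0.0048). In the glia list 3 of 10 members had a region (permutation test, adjusted p = 0.293), those of moody, Gs2 and pnt.

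In each remaining list the adjusted p was 0.86 or more. Mitochondrial ribosomal protein genes had 5 of 73, with mRpL41, mRpS10, mRpL23 and mRpL32 the best ranked, and proteasome genes 1 of 48, at Rpn3. The list of wingless and hedgehog pathway genes had 3 of 24 (slp2, sr and ptc), somatic muscle 3 of 23 (kirre, sls and Mef2), axon guidance and adhesion 4 of 21 (PlexA, sli, Ten-a and Fas3), and neuroblast and neuron identity 2 of 33 (zfh1 and grh). Appendage genes had 2 of 20 (hth and Lim1), neuronal terminal genes 2 of 12 (elav and Syx1A), and hemocyte and fat body genes 2 of 13 (ush and crq). There was 1 member each for Hox genes (Antp), gap and pair-rule genes (slp2), epidermis and cuticle (grh), trachea (rib), germline (piwi) and cell cycle (CycB). Gut and salivary gland genes had 0 of 14. Over all genes, 980 of 13764 (7.12%) had a shared region.

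**Figure D4:**
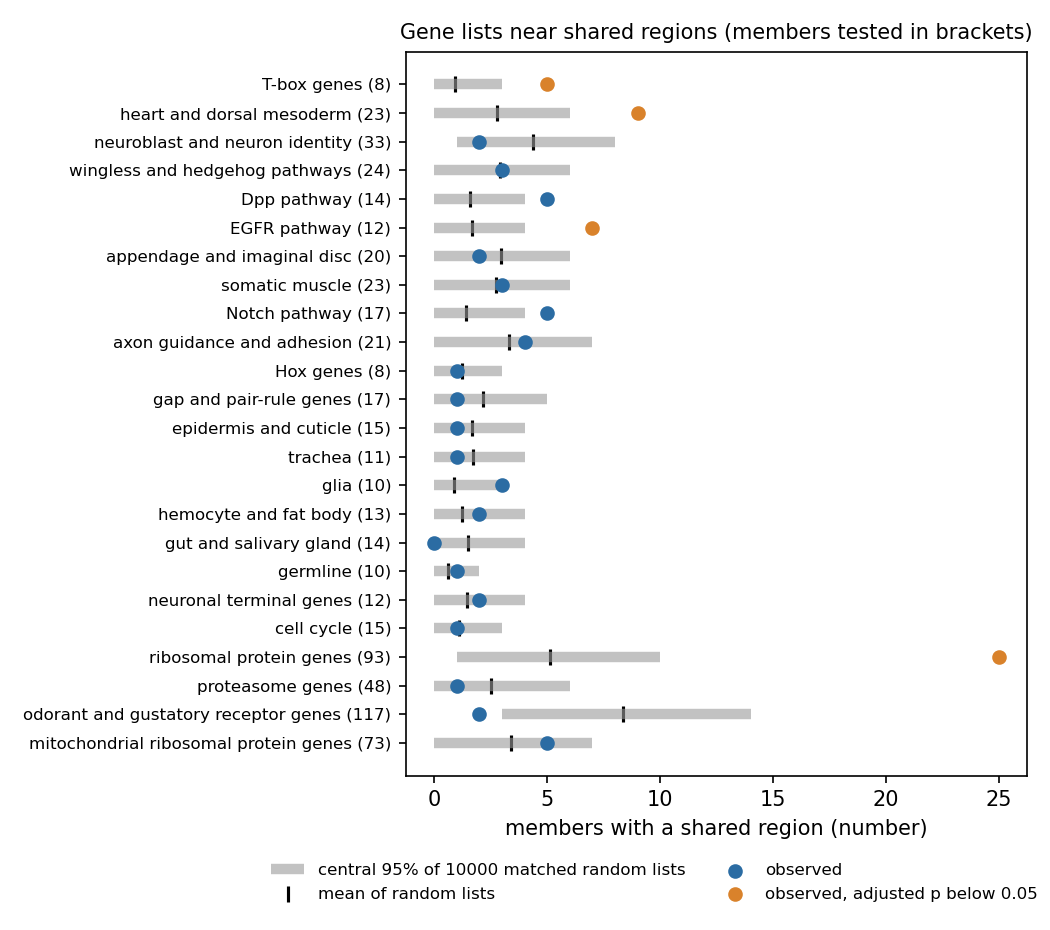
Points give the number of members of each of 24 gene lists with a shared region, grey bars the central 95% of 10000 matched random lists, and ticks their mean. The 4 lists called higher are the T-box list at 5, the heart list at 9, the EGFR list at 7 and the ribosomal list at 25.

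Regions found in a single replicate were compared with shared ones. Promoter regions like those of Ugalt and RpL7 made up 51.8% of shared regions but 19.7% of the 122 regions of replicate 1 alone (odds ratio 4.38, Fisher's exact test, adjusted p = 2.52e-11) and 32.8% of the 262 of replicate 2 alone (odds ratio 2.20, adjusted p = 7.70e-08). They made up 54.8% of the 851 regions of replicate 3 alone, which did not differ detectably (Fisher's exact test, adjusted p = 0.287). The share with the T-box core did not pass the threshold in any replicate (1.64%, 1.91% and 1.18% in single regions, adjusted p = 0.422, 0.287 and 0.66, Fisher's exact test). The shorter core GGTGTG was lower in shared regions than in regions of replicate 3 alone (odds ratio 0.545, Fisher's exact test, adjusted p = 0.00304). It did not differ detectably from regions of replicate 1 alone (odds ratio 0.765, adjusted p = 0.592, Fisher's exact test) or replicate 2 alone (0.892, adjusted p = 0.742).

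The lists of the whole series were longer than the shared set and contained nearly all of it. The conservative list held 3337 peaks, and the other 3 held 2716, 2817 and 4419. Summits within 100 bp of a shared region made up 35.1% of the conservative list (Wilson 95% interval 33.5 to 36.7) and 43.0%, 41.5% and 26.5% of the others. Conversely, 99.3% of the 1178 shared regions had a peak of the conservative list within 100 bp. Between lists, 90.4% of conservative peaks were within 100 bp of a peak of the longest list.

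Last, the locus of the tagged gene was examined. H15 (2L, 5404280 to 5416593) and mid (2L, 5461639 to 5467610) lie between the protein-coding genes nompC and CG14020, from 5365761 to 5517736. This interval held 38 regions, of which 2 were shared by all 3 replicates, 9 were in 2 and 27 were in 1. The shared regions were intergenic, between H15 and mid, from 5425410 to 5425611 and from 5453174 to 5453390. Their signals were 103, 136 and 124.9 for the first and 45.5, 52.6 and 60.7 for the second in replicates 1, 2 and 3. The thresholded lists had 15, 21 and 16 peaks there, and the best ranks were 322, 250 and 496. The interval held 25.0 regions per 100 kb, against 2.20 over all chromosomes.

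**Figure D5:**
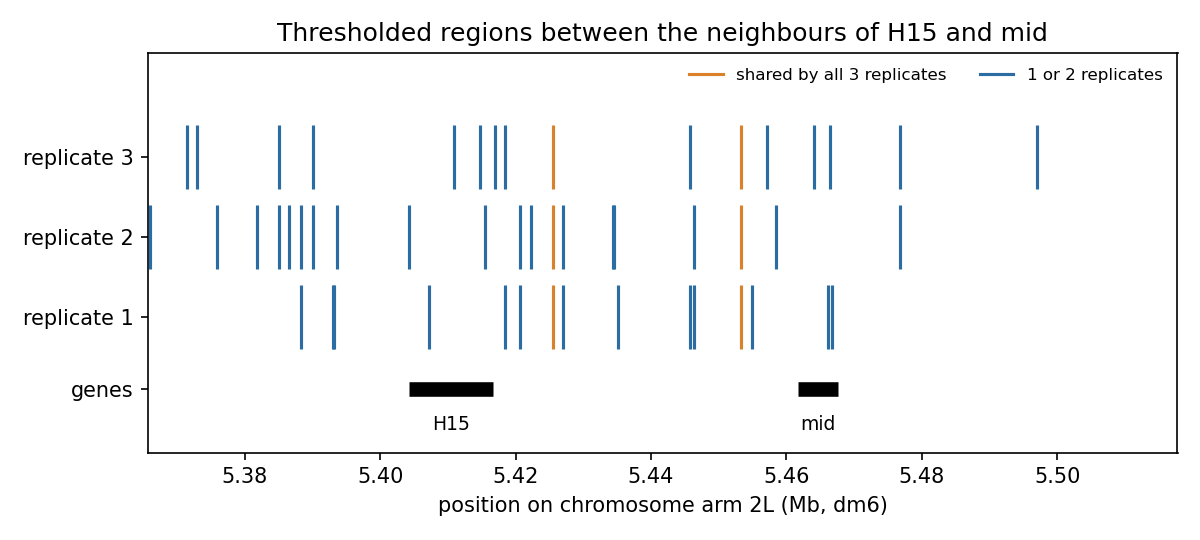
Vertical lines mark the regions of each replicate along 2L, in Mb, between the neighbouring genes of H15 and mid, in colour by whether all 3 replicates share them. Of 38 regions, 2 were shared by all 3 replicates, and both lie between H15 and mid.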

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

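The tests of displaced summits and of the 200 best regions, the limit for the wider search window (a window fixed beforehand), and the counts at H15 and mid without peaks at or near thresholded ones, with the decision to weigh both explanations there by them, were chosen only after the result had been seen.

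Of the 1178 regions shared by all 3 replicates, 9 lay on scaffolds outside the 7 chromosomes, each with a name that begins with X. None of the comparisons of genes, sequence and chromosomes used these 9, so they are not in the count for X. The strongest had signals of 248, 269 and 565 in replicates 1, 2 and 3, and a mean rank of 44.3.

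ACAGTGG, the leading 7-mer, lay beside the centres of shared regions, with 222 sites between 50 and 150 bp away and 37 within 50 bp, a density 5.69 times that at 400 to 600 bp (95% interval 4.40 to 7.37). As to a fixed displacement of the deposited summits, GC content was lowest in the bins on each side of the summit (32.6% and 32.2%). Their centres lie 25 bp away, the smallest distance that bins of 50 bp can give. The dip itself was thus not displaced. But this test takes the dip to mark the true summit and was chosen after the result had been seen, so it does not exclude a displacement. A rise of every word with the same bases is argued against, since the same word read backwards had a ratio of 0.889 (95% interval 0.45 to 1.75). That met the limit set beforehand. But ACAGTGG was picked as the leading of 8192 words in these same regions and the reversed word was not. A lower ratio was thus likely in advance, so the comparison does not exclude other effects of base composition. A sequence with the core CAGTG may mark these regions on both sides of an AT-rich centre, a hypothesis found and tested on the same data. No biological explanation was tested, since the design has 1 group.

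The T-box core AGGTGTG was not higher in shared regions (odds ratio 0.577). Sites within 100 bp of the centre of distal regions, hidden by the many promoter regions, are argued against. Of regions over 500 bp from any start site, 4 of 564 had the core, against 51 of 2820 controls. The odds ratio was 0.388 (95% interval 0.14 to 1.08), with the upper bound below the limit of 1.5 set beforehand. Sites farther from the centre were not covered by this test. Dilution by weak regions stays open, with 1.68 in the 200 best regions (95% interval 0.536 to 5.26, not below 1.5). A search window too narrow for displaced sites stays open too, with an odds ratio of 1.02 at 200 bp on each side (95% interval 0.707 to 1.47). Its limit was an odds ratio of 1, which 1.02 did not meet. Its interval lies below 1.5, but that limit is less strict there, since the wider window takes in more sites in controls (3.02% against 1.62%). Between 50 and 150 bp from the centre the core had 20 sites. Their density was 0.816 times that at 400 to 600 bp (95% interval 0.485 to 1.37), so no rise beside the centre was detected. Against dilution, the odds ratio was 0.860 with the top 500 peaks (95% interval 0.331 to 2.24) and rho between signal and core was -0.0418, -0.0202 and -0.0227 in replicates 1, 2 and 3, but these intervals and permutation tests do not exclude it. The control library was not analysed here, so whether the regions are specific to the fusion protein was not tested.

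The interval of H15 and mid held 38 regions, 71.1% of them in 1 replicate against 40.4% elsewhere (Fisher's exact test, p = 0.000184). Extra copies of the locus carried by the tagged transgene may raise peaks there, and with 20 kb on each side the locus had 349 ranked-list peaks and 100% of the other windows of that length on 2L had fewer (median 221), which met the bound of 95% set beforehand. That count holds the thresholded peaks themselves. Without them 301 were left, more than in 99.7% of windows, but with 100 bp to 2 kb around them left out, the peaks per kb left were above 88.5% to 97.4% of windows, which met the bound at 500 bp and 1 kb and not at 100 bp, 300 bp or 2 kb. For a cluster of sites in a single copy, control peaks were at 1.22 per kb against a median of 1.19, above 54.9% of windows and so under its bound of 95%, but on only 38.7 of 103 kb, and unmerged ranked-list peaks there were above 97.4%. Several regions of 1 replicate at the locus lay in coding exons within H15 or mid. Over all chromosomes this class held 0.903%, 0.362% and 0.610% of the thresholded peaks of replicates 1, 2 and 3, and 19.5% of control peaks. What this means for the locus was not tested. Extra copies and such a cluster cannot be told apart without the reads.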

How the results depend on the processing

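Of 258 values under alternative settings, 195 kept their direction and side of the threshold or stayed within the limits set for counts and shares. Some of the 195 could not change. Random placement of peaks leaves the number of shared regions as it is, and genes added or left out do not alter lists without them, such as the ribosomal list. Agreement of signal (rho 0.803 to 0.842) and the promoter share (odds ratio 4.53 to 10.5) kept both under every alternative run for them. For the promoter share alone, these included controls found in all 3 ranked lists, a choice made after the data had been seen. The number of shared regions was 354 with the top 500 peaks. The T-box odds ratio was above 1 for GGTGTGA (1.28) and with 200 bp on each side (1.02), and was 0.444 against flanking windows and 0.506 without matching (Fisher's exact test, unadjusted p = 0.0125 and 0.0207). Words called higher numbered 62 with 50 bp on each side, 395 with 200 bp, 735 against flanks, 1380 without matching, 500 with the conservative list, 608 with the longest list, 277 with at least 2 replicates and 43 with the top 500 peaks. Words called lower numbered, in the same order, 7, 206, 960, 2224, 428, 532, 170 and 3, with 109 for 6-mers and 138 for controls in all 3 ranked lists. Leaving out each replicate gave 154 to 239 words higher and 43 to 138 lower, the highest of each without replicate 1. Lists called higher numbered 1 within 1 kb of a start site, 2 with the longest list and 0 with the top 500 peaks. The number of lists called lower was 1 with the conservative list, the longest list and at least 2 replicates, and 0 to 1 with a replicate left out (1 without replicate 1 or 2), in each case the odorant and gustatory receptor list. The ratio of the heart list within 1 kb was 0.706 and that of the Notch list with the top 500 peaks 0. The Spearman correlation of rank and T-box core with 50 bp on each side was 0.0254 in replicate 2 and 8.98e-05 in replicate 3. GGTGTG was lower in shared regions than in regions of replicate 3 alone (odds ratio 0.545), with no detectable difference for replicates 1 and 2 (0.765 and 0.892). The number of arms past the threshold was 0 with the top 500 peaks (X 1.23, 3R 0.811), and X was 1.02 with the longest list. The cause of these changes was not tested, except that composition is not held equal in flanks or without matching, and that fewer regions enter with the top 500 peaks. Read depth, which is unknown, may limit all lists, and its effect was not tested.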

Other observations

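All comparisons in this part were chosen after the data had been seen. The core CAGTG was in 601 shared regions (51.4%) and 29.2% of matched control peaks (odds ratio 2.56, 95% interval 2.26 to 2.92). Of the 48 7-mers that contain it, 24 were among the 141 called higher. The core was picked from the leading words, so these values describe the same data and are no independent test. ACAGTGG was in 13.0% of shared regions, against 9.05% of regions of replicate 3 alone (odds ratio 1.502, Fisher's exact test, adjusted p = 0.0167), 9.54% of replicate 2 alone and 8.20% of replicate 1 alone (adjusted p = 0.151 for both). GAGAGA, the repeat bound by the Trl protein, had 323 sites between 50 and 150 bp from the centre and 32 within 50 bp, a density 1.87 times that at 400 to 600 bp (95% interval 1.60 to 2.17). The Trl gene itself had 3 shared regions.

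The regions were not spread evenly. Of 6691 windows of 20 kb, the median held 0 regions of any replicate. Of the 10 densest windows, 4 lay in the interval of H15 and mid, with 8, 7, 7 and 6 regions. The others included 8 regions on 3L from 3380001 to 3400000, next to Ids, and 7 on X from 6840001 to 6860000.

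A small part of the thresholded peaks had low signal values although their IDR passed. A signal under 10 was found for 19 peaks of replicate 1, 41 of replicate 2 and 46 of replicate 3. Each of these peaks lay within 300 bp of a stronger thresholded peak of the same list.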
